A study of Drosophila melanogaster with 13 samples.

How the data were processed

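The series measured RNA of secondary cells from the accessory glands of Drosophila males aged 5 to 11 days. Per the labels, glands were dissected and treated with a protease, GFP-positive cells were sorted, and RNA was extracted from 3 biological replicates each of a wild-type background, the iab-6cocuD1 mutant and a mutant lacking MSAmiP. The labels also give 3 anti-GFP immunoprecipitations of GFP-tagged RPL10Ab (TRAP) and 1 of plain GFP as a control. Libraries were made from 2 ng of RNA with poly(dT) priming (SMARTer) and tagmentation (Nextera XT), which keeps no strand information, and sequenced as single reads of 100 nt. The deposited values are counts of reads per gene, which the authors made by aligning reads to dm6 with STAR and counting with HTSeq. The versions and settings of these tools are not given in the sources used here.

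The table held 16727 gene symbols and 13 libraries, and every column was assigned to a sample from its label, with 0 left unassigned. Current symbols, positions and exonic lengths came from the dm6 annotation of Ensembl release 115: 12512 symbols matched directly and 4010 through a synonym, and 205 did not match, so 16522 genes had coordinates. Library totals lay between 3.701 and 26.09 in units of 1e6 counts. Amplified reads carried no molecular barcodes, so floors and intervals derived from counts cover counting error alone. Where a group had 0 counts the fold change is given as "at least", from a floor of 3 counts over the group.

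Tests were run with edgeR 4.0.16 (quasi-likelihood F-tests) in R 4.3.3, with trimmed mean of M-values (TMM) scaling, the default expression filter and Benjamini-Hochberg adjustment at 0.05. The 9 sorted libraries were fitted together for the contrasts among genotypes. The ribosome immunoprecipitations were fitted with the 3 wild-type sorted libraries, and with the control in a further fit in which the lone control was assumed to vary like the immunoprecipitations. CPM are counts scaled to a library total of 1e6, and normalised CPM are TMM-scaled. Log2 fold changes are those of the edgeR fit at its default settings. The log CPM used for the list tests carry a prior count of 2. Standard errors were derived from the fold change and its F statistic. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 prepared the tables, and matplotlib 3.10.9 drew the figures.

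The groups, contrasts, alternatives and 36 gene lists were chosen before the data were examined. Lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation. Genes were named by a rule fixed beforehand: in each comparison the 10 with the largest positive and the 10 with the largest negative log2 fold change past 0.05, with a mean of at least 5 CPM and no overlap between the libraries of the groups, up to 4 members past 0.05 of each list, and all Bithorax complex genes. The report names a part of these.

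Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of 5 CPM in 3 libraries, a fit of only the groups compared or of all 13 libraries, a test against a log2 threshold of 1 (treat), each library left out in turn, and a block for the replicate number. After replicate 1 of each mutant was seen to stand apart, the fits were repeated without both and with them as groups of their own. Whether replicate numbers pair libraries was checked by correlating each library's deviations from its group mean. Between D1 and miP the same-number values of r were 0.433, 0.169 and 0.312, each above 0.1. The own number gave the highest r for 2 of 3 replicates. Between miP and wild type the values were 0.0065, 0.250 and -0.226, and it also did so for 2 of 3. Replicate 1 stood apart in both mutants, so these values do not settle whether the numbers pair D1 and miP libraries. Between D1 and wild type the same-number values were -0.218, -0.034 and -0.221.

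The pipeline was tested on simulated data with 200 changed genes per comparison. At a 4-fold change it recovered 67% of them for D1 against wild type, 76% for miP against wild type, 67% for D1 against miP, 89% for the immunoprecipitations against sorted cells and 51% against the control. At a 2-fold change it recovered 4, 6, 8, 22 and 2%, and 10.1, 2.38, 2.60, 6.72 and 14.5% of calls were false, in the same order. Changes of 2-fold were therefore mostly missed in these simulations. With DESeq2 the recovery at 4-fold was 93, 90, 89, 96 and 63% in the same order. Of its calls 19.73, 17.69, 11.45, 24.87 and 25% were false, so calls gained with DESeq2 below are less certain.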

Results

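Secondary cells are a minor epithelial cell type at the tip of the Drosophila male accessory gland, where they contribute, beside the more numerous main cells, to the seminal fluid. RNA was sequenced from GFP-positive secondary cells sorted out of 3 genotypes, with 3 libraries each. These were a wild-type background, the iab-6cocuD1 mutant (D1), which carries a lesion named for the iab-6 regulatory domain of the Bithorax complex, and a mutant lacking MSAmiP (miP), a micropeptide encoded by the male-specific iab-8 transcript unit of the same complex. Ribosome-bound RNA was also isolated by anti-GFP immunoprecipitation (TRAP) from glands with a GFP-tagged RPL10Ab in the driver's cells, in 3 libraries, with 1 control library from glands with plain GFP. Counted reads, in units of 1e6, came to 23.5, 21.2 and 26.09 in wild type, 20.99, 19.4 and 21.3 in D1, and 18.6, 20.8 and 18.2 in miP. The ribosome immunoprecipitations (IPs) held 11.2, 21.4 and 17.4 and the control 3.701.

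A handful of genes, several of them for secreted products, took most of the counts of the wild-type cells. CG9029, a gene of unknown function on chromosome arm 2L (dm6 5886002 to 5886609), took 31.7% of all counts (317126 ± 11470 CPM, counts scaled to a total of 1e6; SD, n = 3). Acp32CD, an accessory gland protein, followed with 13.9%, and then 3 proteins that females need to retain Sex Peptide after mating, the cysteine-rich secretory protein CG17575 with 10.2%, lectin-46Cb with 8.56% and lectin-46Ca with 7.14%. CG13965 took 1.74%, the secreted adhesion protein mfas 1.54%, the chaperone Hsp83 0.639% and Arc1, which forms virus-like capsids, 0.476%. The 10 most abundant genes together held 75.7, 76.3 and 77.0% of the counts of the 3 libraries. In the ribosome IPs CG9029 was again the most abundant gene with 9.27% (92714 ± 18373 CPM, SD, n = 3), against 0.594% in the control, and Acp32CD (2.74%), CG17575 (2.02%), lectin-46Ca (1.62%) and lectin-46Cb (0.665%) were among the 10 most abundant. The IPs also held genes near 0 in sorted cells, such as the CAP-family genes scpr-C (1.51%; 2.89 CPM in sorted cells) and scpr-A, and the odorant-binding proteins Obp99a (1.01%) and Obp44a (0.771%). A ribosomal RNA pseudogene, CR41602, took 3.63%, an uncertain value because near-identical copies share its reads.

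At 1 CPM in all 3 libraries, 6210 genes were detected in wild-type sorted cells and 10518 in the ribosome IPs. The IPs shared 5984 of them, or 96.4% of the sorted-cell genes, while 226 were detected in sorted cells alone and 4534 in the IPs alone. The single IPs held 11216 to 11445 genes at 1 CPM, and the control without tagged ribosomes held 11305. Detection in the IPs therefore does not by itself show that an RNA was bound to tagged ribosomes.

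The question of the D1 comparison is which transcripts of the secondary cell depend on the region that the D1 lesion removes. The Bithorax complex itself showed the sharpest loss. The Hox gene abd-A, on 3R at 16807214 to 16830049 (dm6), stood at 175, 202 and 210 CPM in the wild-type libraries and at 0.0476, 0 and 0.0938 in D1, which is 3 counts in D1 against 13871 (normalised CPM 0.0373 ± 0.0325 against 241 ± 27.1, SD, n = 3 each; adjusted p = 8.40e-07). The iab-8 transcript unit, annotated as non-coding, runs from 16831116 to 16923231, and its counts include the male-specific abdominal transcript msa. The unit fell 18.8-fold (log2 fold change -4.24 ± 0.24, SE; adjusted p = 1.24e-05). It held 955, 759 and 804 CPM in wild type and 45.03, 86.0 and 91.3 in D1. The non-coding iab-4 transcript fell at least 782-fold, from 20.2, 26.7 and 23.1 CPM to 0 counts in every D1 library (adjusted p = 1.85e-05). It lies inside iab-8 on the opposite strand, and the counts of such overlapping genes cannot be separated without strand information.

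The loss extended proximally from abd-A. The non-coding bxd transcript, next to Ubx, fell at least 49.0-fold (adjusted p = 5.16e-04) and Glut3, a sugar transporter gene within the complex at 16788311 to 16790021, at least 390-fold (adjusted p = 2.85e-05). The non-coding RNAs CR45750 and CR45751, which lie between Glut3 and abd-A and were chosen after their values were seen, fell at least 116-fold and 142-fold, with 0 counts in D1. The outermost Hox genes differed less: Ubx had a log2 fold change of -0.65 ± 0.25 (adjusted p = 0.152) and Abd-B, at 119, 102 and 96.4 CPM in wild type and 133, 127 and 166 in D1, one of -0.21 ± 0.26 (adjusted p = 0.722). The negative sign of Abd-B comes from the TMM factors, which were 0.831, 0.813 and 0.798 in wild type and 0.905, 1.52 and 1.58 in D1. Ubx did pass the threshold without D1 replicate 1 (log2 fold change -0.97, adjusted p = 0.00141). Of the 6 tested genes of the Bithorax complex list, 4 fell over all genes tested and 5 when adjusted over the list alone, with a median log2 fold change of -6.26, or -4.93 with genes at 0 held at their bound. The list stood below other genes (adjusted p = 9.53e-09; adjusted p = 0.256 with an estimated correlation). The 8 tested secondary cell factors, which overlap with that list in abd-A and iab-8, had 2 falling genes, those same 2, and 3 when adjusted over the list alone, with a median of -0.23 (adjusted p = 0.00263; adjusted p = 0.520 with an estimated correlation).

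**Figure D1:**
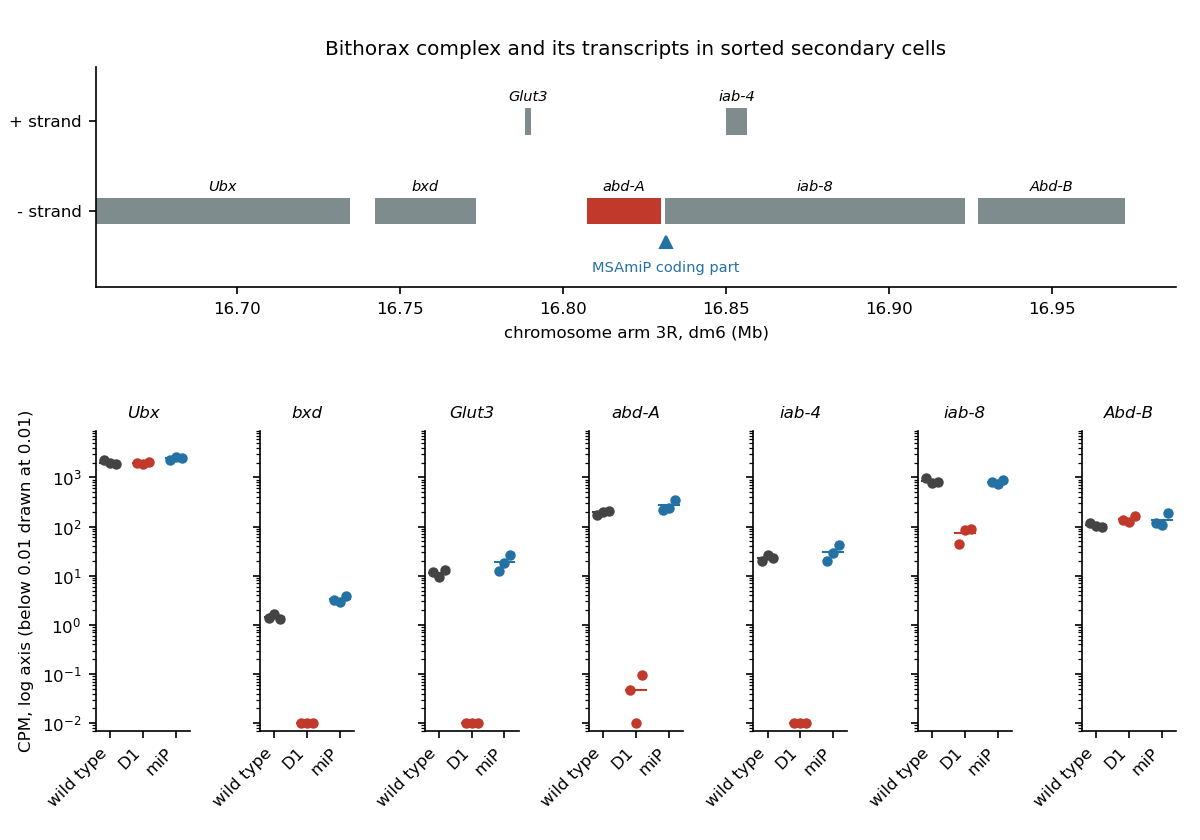
Map of the Bithorax complex on 3R (dm6, position in Mb, genes by strand, abd-A in red, the coding part of MSAmiP as a triangle) above the level of each gene (CPM, log axis, values below 0.01 drawn at 0.01) in 3 wild-type, 3 D1 and 3 miP sorted libraries (points; lines are means). From bxd to iab-4 the D1 libraries lie at or near 0, iab-8 is lower, and Ubx and Abd-B lie near the wild-type level.

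Over 8222 genes tested, 505 were higher and 298 lower in D1 than in wild type. Beyond the Bithorax complex, large losses included CR40469, a short non-coding RNA (log2 fold change -9.69 ± 0.86, adjusted p = 1.39e-04), and several protein-coding genes. CG31690 (Tmtc1, of a family of ER membrane mannosyltransferases) fell by 10.61 ± 0.39 on the log2 scale, from 85.1 to 0.0486 normalised CPM (adjusted p = 6.77e-07). CG13822 (GILT3, a gamma-interferon-inducible thiol reductase homologue) fell 171-fold (adjusted p = 1.85e-05), from 983 ± 46.6 to 5.77 ± 2.38 normalised CPM. CG15864 fell 94.7-fold and Gal, a beta-galactosidase, 52.0-fold (adjusted p = 2.97e-05).

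A few stress-induced chaperones fell as well. Of 16 tested members of that list, 4 fell over all genes tested and 7 when adjusted over the list alone, and none rose, with a median log2 fold change of -0.58 (adjusted p = 3.87e-04; adjusted p = 0.530 with an estimated correlation). The list's share of counts before scaling was 1.998% in wild type and 2.034% in D1. The 4 were Hsp70Ba, 8.08-fold lower (log2 fold change -3.01 ± 0.32, adjusted p = 3.58e-04), the co-chaperone stv, 5.15-fold lower (adjusted p = 2.50e-04), DnaJ-1, 4.23-fold lower (adjusted p = 0.00198), and the heat-inducible non-coding RNA Hsromega (-1.49 ± 0.25, adjusted p = 0.00491). Hsp70Ba shares reads with near-identical Hsp70 copies, so its own level is uncertain.

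Of the seminal fluid products, few passed. In the Sex Peptide network list 2 of 9 genes fell, lectin-46Cb (log2 fold change -1.17 ± 0.23, adjusted p = 0.00998) and lectin-46Ca (-1.16 ± 0.26, adjusted p = 0.0176), and the same number when adjusted over the list alone. The list had a median of -0.68 (adjusted p = 0.332). Before scaling it took 25.91% of counts in wild type and 20.64% in D1. The TMM factors lowered D1 values relative to wild type, so the falls given here are larger than before scaling. Acp32CD (-1.21 ± 0.25, adjusted p = 0.0136) was the only one past the threshold of 19 main cell and classical accessory gland proteins, called main cell genes here. This also held when adjusted over the list alone. In the sorted wild-type cells Acp32CD took 13.89% of counts, nearly all of the list's 13.96%, so its fall is not one of main cells alone. The list took 9.457% of counts in D1. That list's median was -0.41 while its test leaned upward (adjusted p = 0.943). The serpin Spn28B (-1.62 ± 0.27, adjusted p = 0.00404) was the only one of 40 other seminal fluid proteins, also when adjusted over the list alone (median -0.55, adjusted p = 0.876). Main cell genes differed within groups, lower in wild-type replicate 1 than in replicates 2 and 3 by a median of -5.55 (0 of 19 above 0) and higher in D1 replicate 1 by 2.47 (19 of 19). The lectin-46Cb call was lost without wild-type replicate 2 (adjusted p = 0.0530) or 3 (0.0520), and that of Acp32CD without D1 replicate 2 (0.0545) or wild-type replicate 1 (0.0503), 2 (0.0636) or 3 (0.0619). That of lectin-46Ca was lost without D1 replicate 2 (0.0701) or 3 (0.0634) or wild-type replicate 1 (0.0596), 2 (0.0736) or 3 (0.0765).

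Some genes of protein folding in the endoplasmic reticulum rose in D1. Of 27 tested ER chaperone and unfolded protein response genes, 11 rose over all genes tested, 14 when adjusted over the list alone, and none fell, with a median log2 fold change of 0.75 (adjusted p = 2.97e-06; adjusted p = 0.430 with an estimated correlation). Among them wbl, an ER protein of the disulfide isomerase family, rose 8.24-fold (log2 fold change 3.04 ± 0.38, adjusted p = 9.29e-04), the lectin chaperone Cnx99A 4.69-fold (2.23 ± 0.22, adjusted p = 2.41e-04) and protein disulfide isomerase Pdi 4.34-fold (2.12 ± 0.27, adjusted p = 9.98e-04).

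Neighbouring parts of the secretory route showed single genes past the threshold without a list-wide call. Of 38 genes of ER translocation and vesicle coats 5 rose, 8 when adjusted over the list alone, with a median of 0.40 (adjusted p = 0.0751). Of 43 glycosylation genes 6 rose and none fell, with 13 rising and 2 falling when adjusted over the list alone and a median of 0.39 (adjusted p = 0.0878). With replicate 1 of both mutants left out both lists passed (adjusted p = 0.0298 and 0.0152). With all libraries and an estimated correlation neither did (adjusted p = 0.430 and 0.929).

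Several genes that rose strongly were near 0 in wild type. Ndg (nidogen, a basement membrane protein) rose 147-fold (log2 fold change 7.20 ± 0.97, adjusted p = 0.00134), from 0.670 to 98.6 normalised CPM. The prohormone convertase chaperone 7B2 (6.15 ± 0.78, adjusted p = 9.67e-04), the secreted BMP antagonist sog (6.11 ± 0.94, adjusted p = 0.00276), Syn2 (syntrophin-like, 5.78 ± 0.76, adjusted p = 0.00116), the carbonic anhydrase CAH1 (5.71 ± 0.39, adjusted p = 2.85e-05) and the octopamine receptor Octbeta2R (5.70 ± 0.89, adjusted p = 0.00289) rose likewise. Each of these lay under 3 normalised CPM in wild type.

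Transport genes were a further group. Of 31 ion channels and pumps 5 rose, 6 when adjusted over the list alone, and none fell, with a median of 0.82 (adjusted p = 0.00772; adjusted p = 0.629 with an estimated correlation). The 5 included the sodium channel subunit ppk20 (3.17 ± 0.47, adjusted p = 0.00216) and the Na,K-ATPase subunit nrv2 (1.86 ± 0.24, adjusted p = 0.00116). Of 44 solute carriers 5 rose and 1 fell, 9 and 3 when adjusted over the list alone, with a median of 0.29 (adjusted p = 0.177). The proton exchanger Nhe3 rose 4.97-fold (adjusted p = 1.40e-04) and the amino acid transporter path 5.03-fold (adjusted p = 0.00143). Among 24 cell cycle genes 3 rose, PCNA (3.96 ± 0.57, adjusted p = 0.00185) and both ribonucleotide reductase subunits RnrS (4.28 ± 0.72, adjusted p = 0.00452) and RnrL (2.32 ± 0.35, adjusted p = 0.00230), and the kinase aur fell (-1.86 ± 0.25, adjusted p = 0.00126). The counts were the same when adjusted over the list alone and the list's test gave adjusted p = 0.332 (median 0.14). The Hox cofactor exd rose 3.65-fold (adjusted p = 0.00217).

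**Figure D2:**
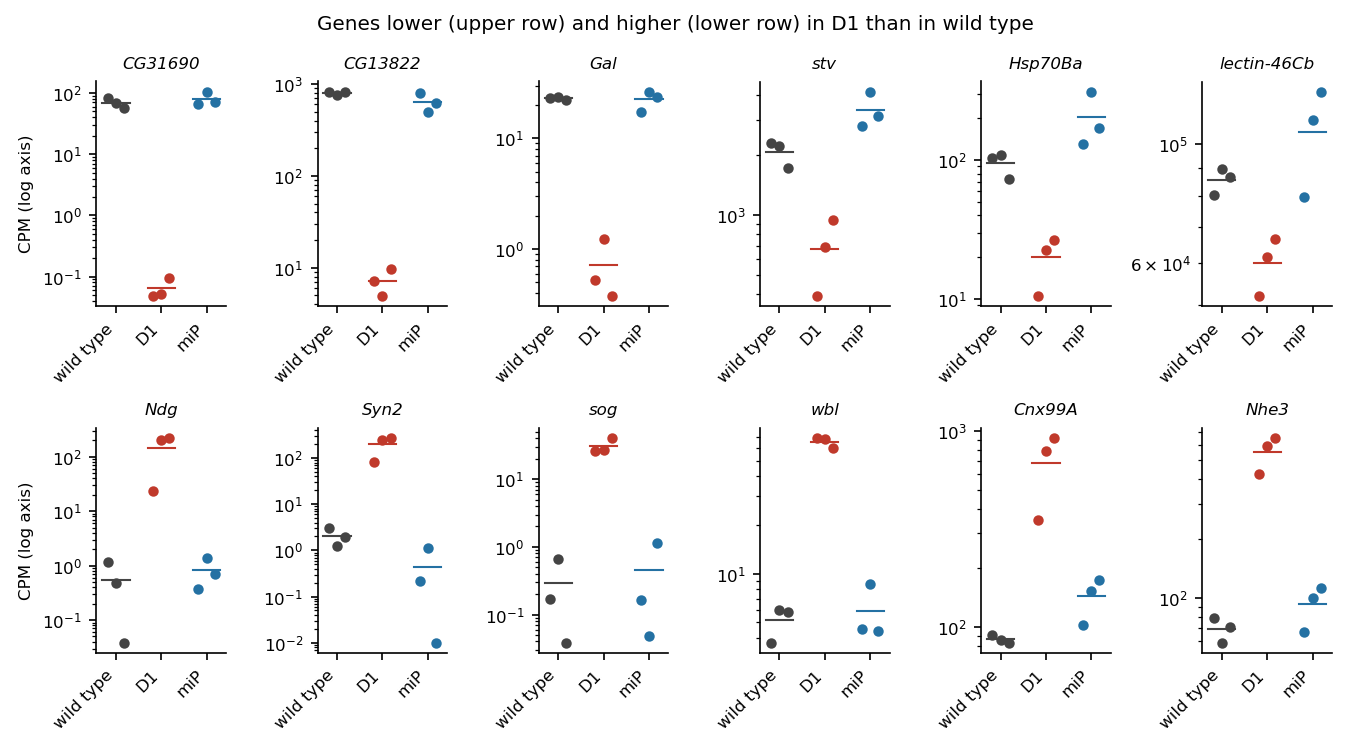
Level of 12 genes (CPM, log axis) in each sorted library of wild type, D1 and miP (3 points per group, lines at the means). Genes in the upper row were lower in D1 and those in the lower row higher, and the miP points lie on the wild-type side in each panel.

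Replicate 1 of D1 stood apart from replicates 2 and 3 in parts of this comparison. Its 10 most abundant genes held 72.5% of the counts, against 58.2 and 56.3% in replicates 2 and 3, and CG9029 alone 38.7% against 13.8 and 14.3%. Relative to them, cytosolic ribosomal protein genes were higher in it by a median of 1.53 on the log2 scale (85 of 85 genes) and nuclear oxidative phosphorylation genes by 1.42 (56 of 68). Against wild type the 85 ribosomal genes had a median of -0.42, with 1 gene falling, RpL22, and 0 when adjusted over the list alone (adjusted p = 4.99e-05; adjusted p = 0.944 with an estimated correlation). Before scaling, the list's mean share of counts went the other way, from 1.771% in wild type to 1.932% in D1. The 68 oxidative phosphorylation genes had none past the threshold, 0 when adjusted over the list alone, and a median of 0.23 (adjusted p = 0.511). Before scaling, the oxidative phosphorylation list took 0.418% of counts in wild type and 0.814 ± 0.0646% in D1 (SD). With replicate 1 of both mutants left out, the ribosomal list stood further down (adjusted p = 7.87e-19), so its fall was carried by replicates 2 and 3. The oxidative phosphorylation list then turned downward (adjusted p = 0.00604), against the direction of its share before scaling. In that setting fold changes rose with exonic length (Spearman rho 0.396 across genes), with a median of 3184 nt for higher and 1232 nt for lower genes. Of 31 proteasome genes 3 fell by less than 1 on the log2 scale, Rpn6, Rpt2 and Rpn8, and 3 when adjusted over the list alone, with a median of -0.36 (adjusted p = 0.0358; adjusted p = 0.844 with an estimated correlation). Before scaling, the proteasome list took 0.242% of counts in wild type and 0.331% in D1, so its fall appears only after scaling.

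Single libraries moved the D1 counts. Without D1 replicate 1, 1093 genes were higher and 1002 lower. Without D1 replicate 2 or 3 the counts were 332 and 346 higher and 155 and 166 lower, and without wild-type replicate 1, 2 or 3 they were 271, 247 and 233 higher and 144, 140 and 137 lower. The calls of RpL22, Rpn6, Rpt2 and Rpn8 were lost without any 1 of D1 replicates 2 and 3 or the wild-type libraries, with adjusted p from 0.0614 to 0.196. That of RpL22 was also lost with RLE (adjusted p = 0.0654) and upper-quartile factors (0.0582), and that of Rpn8 with RLE factors (0.0632). The other genes named for D1 above kept their call without any 1 library, apart from the seminal fluid products given with their values.

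Removing the micropeptide left the sorted-cell transcriptome much closer to wild type. The comparison asks what the MSAmiP peptide itself does, apart from the transcript that encodes it. Its coding part lies in exon 8 of the annotated gene, at 16831514 to 16831573 on 3R, and the deletion cannot be checked from a count taken over the whole iab-8 unit. That unit held 818, 720 and 879 CPM in miP (log2 fold change -0.27 ± 0.21). None of the 6 Bithorax complex genes passed the threshold: abd-A stood at 0.23 ± 0.28, Abd-B at 0.16 ± 0.26, Ubx at 0.07 ± 0.25, iab-4 at 0.11 ± 0.26 and bxd at 0.96 ± 0.44, with adjusted p from 0.940 to 0.962.

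Over the 8222 genes, 2 were higher and 5 lower in miP, with 292 at an unadjusted p under 0.05. CR40469, near the tip of the X chromosome (122493 to 122706), was nearly lost. It held 1114, 1257 and 1018 CPM in wild type and 1.83, 1.105 and 1.04 in miP (log2 fold change -9.91 ± 0.87, adjusted p = 0.00281). D1 had the same loss, to 3.53, 0.722 and 1.31 CPM (-9.69 ± 0.86, adjusted p = 1.39e-04). CG9119, chosen after its values were seen, fell from 216 counts in wild type to 2 (-6.51 ± 0.60, adjusted p = 0.00281) and ppk20 from 147 counts to 1 (-6.73 ± 0.80, adjusted p = 0.0198). The synaptic vesicle protein nSyb fell 4.07-fold (-2.03 ± 0.29, adjusted p = 0.0487) and the actin-capping protein tmod 2.65-fold (adjusted p = 0.0481). The 2 higher genes, CG33080 (59.5-fold, adjusted p = 0.0338) and CG13360 (4.01-fold, adjusted p = 0.0198), both lie on the X chromosome, as CR40469 does.

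**Figure D3:**
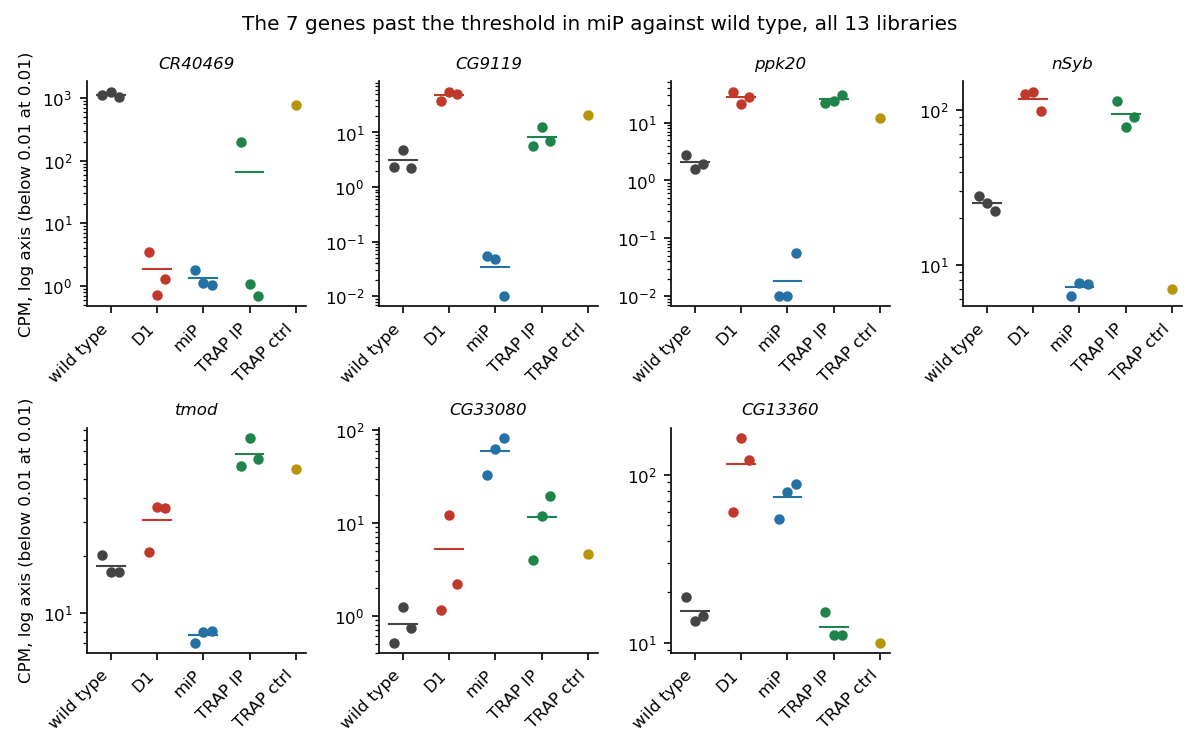
Level (CPM, log axis, values below 0.01 drawn at 0.01) of the 7 genes past the threshold between miP and wild type, in all 13 libraries (points; lines are means of groups of 3). CR40469 is near 1 in both mutants and in ribosome IPs 2 and 3, and high in IP 1 and in the control.

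In 3 gene lists the test over the list passed while no single gene did. Of the 16 stress-induced chaperones none passed, 0 when adjusted over the list alone, yet their median was 0.40 in miP (adjusted p = 6.46e-06; adjusted p = 0.430 with an estimated correlation), opposite to their direction in D1. The 85 ribosomal genes (median -0.30, adjusted p = 1.17e-04; adjusted p = 0.944 with an estimated correlation) and the 68 oxidative phosphorylation genes (median -0.32, adjusted p = 0.0138; adjusted p = 0.944 with an estimated correlation) had none past the threshold, 0 when adjusted over each list alone. Before scaling, the ribosomal list took 1.771% of counts in wild type and 1.643% in miP, and the oxidative phosphorylation list 0.418% and 0.433%. Both lists were higher in miP replicate 1 than in miP replicates 2 and 3, by medians of 1.09 (84 of 85 genes) and 0.69 (56 of 68). Without replicate 1 of both mutants they stood further down (adjusted p = 9.49e-20 and 3.14e-08). Fold changes of miP over wild type rose with exonic length (Spearman rho 0.376 across genes, 0.399 without replicate 1).

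The 7 miP calls are sensitive to single libraries. Without miP replicate 2 there were none (CR40469 and CG9119 each at adjusted p = 0.0539). Without miP replicate 1 or 3 or wild-type replicate 1 or 3 there were 0 higher and 2 lower, and without wild-type replicate 2, 0 and 3. With replicate 1 of both mutants left out there were 361 higher and 632 lower. The calls of nSyb (adjusted p = 0.0646 and 0.0843) and tmod (0.0582 and 0.0560) were also lost with RLE and upper-quartile factors, and those of CG33080, CG13360, nSyb and tmod without any 1 library. That of ppk20 was lost without miP replicate 1 (adjusted p = 0.0968), 2 (0.126) or 3 (0.160) or wild-type replicate 1 (0.0731) or 3 (0.0701).

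The direct contrast of D1 with miP tests whether the effects of the 2 lesions differ, and 554 genes were higher and 313 lower in D1. The same Bithorax genes fell relative to miP, iab-8 by 3.97 ± 0.24 on the log2 scale (adjusted p = 1.49e-05), iab-4 at least 860-fold, bxd at least 95.0-fold and Glut3 at least 534-fold, and abd-A held 15505 counts in miP against 3 in D1 (adjusted p = 7.35e-07). The Bithorax list had 4 of 6 genes falling, 5 when adjusted over the list alone, and a median of -6.61, or -5.27 with genes at 0 held at their bound (adjusted p = 7.30e-09; adjusted p = 0.256 with an estimated correlation). Of the 8 secondary cell factors 2 fell, abd-A and iab-8, 2 when adjusted over the list alone, with a median of -0.19 (adjusted p = 0.0130; adjusted p = 0.629 with an estimated correlation). Ubx did not pass (-0.72 ± 0.25, adjusted p = 0.108), but did with the replicate numbers as a block in the 6 mutant libraries (-0.76, adjusted p = 0.0495) and without D1 replicate 1 (-1.03, adjusted p = 0.00106).

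Stress-induced chaperones differed between the mutants as well. Of 16 genes 8 were lower in D1 than in miP, 8 when adjusted over the list alone, and none higher, with a median of -0.98 (adjusted p = 6.47e-08; adjusted p = 0.430 with an estimated correlation). Hsp70Ba was 14.7-fold lower (-3.88 ± 0.34, adjusted p = 8.18e-05), stv 7.13-fold and DnaJ-1 5.45-fold. ER folding genes went the other way, with 9 of 27 higher in D1, 14 when adjusted over the list alone, none lower, and a median of 0.62 (adjusted p = 1.00e-04; adjusted p = 0.430 with an estimated correlation), among them wbl (8.53-fold) and Pdi (3.86-fold). Of the 38 translocation and coat genes 8 were higher, 10 when adjusted over the list alone (median 0.44, adjusted p = 0.0534; with the replicate block adjusted p = 0.0448; adjusted p = 0.430 with an estimated correlation). Of 31 ion channels and pumps 7 were higher and 1 lower, 9 and 2 when adjusted over the list alone (median 0.52, adjusted p = 0.0141; adjusted p = 0.685 with an estimated correlation).

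Of 14 immediate early and JNK pathway genes 4 were higher and 1 lower, 6 and 2 when adjusted over the list alone (median 1.05, adjusted p = 0.0833), with the Fos homologue kay (1.95 ± 0.23, adjusted p = 6.48e-04) and the matrix metalloprotease Mmp1 (1.95 ± 0.25, adjusted p = 8.65e-04) each 3.86-fold higher. The 68 oxidative phosphorylation genes had a median of 0.52, with 2 higher, CG9350 and SdhC, and 0 when adjusted over the list alone (adjusted p = 0.0205; adjusted p = 0.944 with an estimated correlation). That call was lost with replicate 1 of both mutants left out (adjusted p = 0.273), the libraries with which this list goes. Among the largest single differences, Skeletor was 46.2-fold lower in D1 (43.8 ± 17.6 against 2023 ± 447 normalised CPM, SD, n = 3 each) and the cytochrome P450 gene Cyp6d5 39.8-fold lower. Higher in D1 were CG11550, at least 210-fold (0 counts in miP), and the synapse-associated protein Sap47, 77.6-fold (6.28 ± 0.74, adjusted p = 6.15e-04).

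Without D1 replicate 1 this contrast gave 907 higher and 614 lower genes. Without D1 replicate 2 or 3 it gave 362 and 402 higher and 191 and 223 lower, and without miP replicate 1, 2 or 3 it gave 377, 334 and 369 higher and 222, 201 and 198 lower.

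The mutants' calls against wild type overlapped in 1 higher gene, CG13360, and 1 lower gene, CR40469, where independent lists of these sizes would share 0.123 and 0.181. A further 3 genes passed in opposite directions: CG9119 (3.25 in D1 and -6.51 in miP), nSyb (1.64 and -2.03) and ppk20 (3.17 and -6.73). Across the 8222 genes, which are not independent replicates, the 2 sets of fold changes correlated with r = 0.201. The shared controls alone gave a mean r of 0.501 in 20 simulated data sets, which held a mean of 7642 genes. No gene was changed in those sets, so their r cannot be compared with that of data in which many genes differed in D1. The covariance was 0.175, against a simulated mean of 0.152 and a highest value of 0.167. The 3 control libraries cannot be split, so part of any excess may come from them, and part from any pairing of the mutants' replicate numbers, which the simulation left out.

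The comparison of the ribosome IPs with their control asks which RNAs were bound to tagged ribosomes of the driver's cells. Of 12723 genes tested, 414 were higher and 34 lower in the IPs. The bait gene RpL10Ab stood at 552, 978 and 1620 CPM in the IPs and 349 in the control (log2 fold change 1.95 ± 0.55, adjusted p = 0.108). Among the Bithorax genes the iab-8 unit rose 83.2-fold on the ribosomes (129 ± 45.6 normalised CPM, SD, n = 3, against 1.55; adjusted p = 0.0216). This unit is annotated as non-coding, but the coding part of MSAmiP lies within it. The protein-coding abd-A (2.09 ± 0.47, adjusted p = 0.0624), Abd-B (0.31 ± 0.84, adjusted p = 0.867) and Ubx (-2.004 ± 0.68, adjusted p = 0.165), and bxd (-0.08 ± 1.44, adjusted p = 0.982), did not pass. The 10 secondary cell factors had 1 higher and 1 lower gene, iab-8 and the transcription factor vvl (-2.23 ± 0.41, adjusted p = 0.0364), with 5 and 1 when adjusted over the list alone (median 1.15, adjusted p = 0.0517).

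Of the 5 most abundant products of the sorted cells 3 were enriched. CG9029 was 20.4-fold higher in the IPs (4.35 ± 0.53, adjusted p = 0.0216), lectin-46Ca 14.03-fold (3.81 ± 0.68, adjusted p = 0.0355) and CG17575 13.8-fold (3.78 ± 0.70, adjusted p = 0.0378). Acp32CD (3.66 ± 1.01, adjusted p = 0.103) and lectin-46Cb (2.71 ± 0.72, adjusted p = 0.0945) did not pass. Of the 100 genes most abundant in sorted cells 84 had a log2 fold change above 0, 17 were past the threshold as higher and 0 as lower. Of the 414 higher genes 65.7% were detected in wild-type sorted cells, against 48.1% of the other genes tested (odds ratio 2.07, Fisher's exact test, p = 1.19e-12, across genes). Of the 34 lower genes 2 were detected there. No level cut was applied, and being called and being detected can both rise with abundance. Across the genes tested, sorted-cell level and fold change had a Spearman rho of 0.116.

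Septate junction genes, which seal the spaces between epithelial cells, included enriched members. Of 25 genes 7 were higher, 15 when adjusted over the list alone, and none lower, with a median of 1.83 (adjusted p = 1.59e-05; adjusted p = 0.809 with an estimated correlation). They included the claudin sinu, 9.69-fold higher (3.28 ± 0.41, adjusted p = 0.0216), CG7713 (pasi1, 8.50-fold), CG8121 (pasi2, 7.12-fold) and Tsf2 (melanotransferrin, 6.20-fold). Of 30 Rab GTPases 2 were higher, RabX4 (2.79 ± 0.43) and Rab10, 8 when adjusted over the list alone, with a median of 0.72 (adjusted p = 0.00652; adjusted p = 0.530 with an estimated correlation). Of 56 solute carriers 8 were higher, 13 when adjusted over the list alone, with a median of 0.51 (adjusted p = 0.0369; adjusted p = 0.844 with an estimated correlation), among them the zinc transporter Zip88E (16.8-fold) and the amino acid transporter slif (11.0-fold). Of 14 stress-induced chaperones 1 was higher, Hsp23 (3.87 ± 0.69, adjusted p = 0.0354), 2 when adjusted over the list alone, with a median of 1.28, or 1.11 with genes at 0 at their bound (adjusted p = 0.0224; adjusted p = 0.892 with an estimated correlation). The synaptic protein nSyb was 17.7-fold higher (4.14 ± 0.45, adjusted p = 0.0216) and the BMP ligand gbb 3.85-fold (adjusted p = 0.0272).

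Several enriched genes were absent from the control. CG32557 (Mco4, a multicopper oxidase) was at least 755-fold higher (499 ± 27.4 normalised CPM, SD, n = 3; adjusted p = 0.00145), 7B2 at least 48.4-fold, the cuticle protein TwdlD at least 29.8-fold and the O-glycan galactosyltransferase C1GalTA at least 22.9-fold. The steroidogenic P450 gene sad was 367-fold higher (8.52 ± 1.07, adjusted p = 0.0216), and sorted wild-type cells held under 1 CPM of it and of CG32557.

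A few main cell and other seminal fluid genes were lower. Of 52 seminal fluid proteases, serpins and related proteins 2 were higher and 3 lower, 2 and 11 when adjusted over the list alone, with a median of -0.76 (adjusted p = 6.47e-08; adjusted p = 0.685 with an estimated correlation). Of 20 main cell genes 1 was lower, Acp29AB (-1.36 ± 0.24, adjusted p = 0.0352), also 1 when adjusted over the list alone, with a median of -0.57 (adjusted p = 0.00356; adjusted p = 0.844 with an estimated correlation). The 26 testis and sperm genes (median -0.24, adjusted p = 0.0369; adjusted p = 0.685 with an estimated correlation) and the 30 cell cycle genes (median -0.26, adjusted p = 0.0490; adjusted p = 0.844 with an estimated correlation) had none past the threshold, 0 when adjusted over each list alone. Of 10 ejaculatory duct and bulb genes 4 were lower and 1 higher, 6 and 3 when adjusted over the list alone (median -2.02, adjusted p = 0.0833). The lower ones included glucose dehydrogenase Gld (-2.67 ± 0.33, adjusted p = 0.0216) and the esterase Est-6 (-2.17 ± 0.28, adjusted p = 0.0216), both known from the duct, and the higher one was the serpin Spn75F (16.8-fold).

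**Figure D4:**
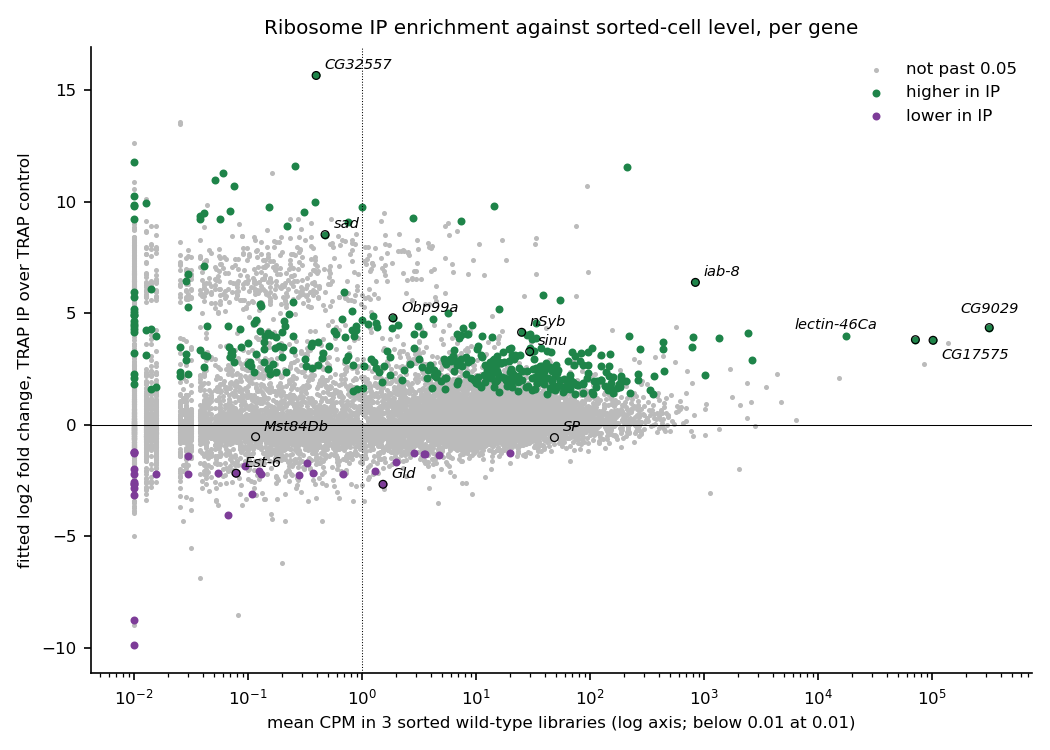
Fitted log2 fold change of each gene in the 3 ribosome IPs over the control library (vertical axis) against its mean CPM in the 3 wild-type sorted libraries (horizontal log axis, values below 0.01 drawn at 0.01, dotted line at 1). Coloured points are the 414 higher and 34 lower genes, and the abundant products of sorted cells lie at the upper right.

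These IP calls rest on 1 control library, assumed to vary like the IPs, and on IP replicate 3. Without IP replicate 3 only 1 gene was called, CG32557, while fold changes kept their size: iab-8 stood at 6.12 (adjusted p = 0.0510), CG9029 at 4.40 (0.0510), sinu at 3.13 (0.0560) and Gld at -2.48 (0.0558). Without IP replicate 1 there were 1433 higher and 481 lower genes, and without IP replicate 2, 631 and 85. With all 13 libraries in the fit CG9029 (adjusted p = 0.0640), Gld (0.167), Est-6 (0.0826), Acp29AB (0.771), vvl (0.222), Spn75F (0.429), slif (0.189), Tsf2 (0.107), RabX4 (0.0636), TwdlD (0.0649) and C1GalTA (0.0912) did not pass, and with DESeq2 RpL10Ab (6.86e-04) and abd-A (0.0183) did. Without IP replicate 1, RpL10Ab (2.22, adjusted p = 2.05e-05), abd-A (2.07, adjusted p = 0.00831) and Ubx (-2.83, adjusted p = 1.61e-05) passed as well.

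The ribosome IPs and the sorted wild-type cells differed in most genes, with 5705 higher and 3656 lower of 11621. The question here is how far 2 isolation methods give the same picture of a cell type, and the methods also differ in genotype, protease treatment and sorting. Fold changes fell with exonic length (Spearman rho -0.419 across genes), with a median of 1332 nt for genes higher in the IPs and 2621 nt for lower ones. The IPs held many transcripts of other reproductive tissue. Of 26 testis and sperm genes 25 were higher and none lower, with a median of 9.99, or 9.74 with genes at 0 at their bound (adjusted p = 1.46e-06; adjusted p = 0.352 with an estimated correlation). The sperm chromatin protein Mst35Bb went from 1 count in sorted cells to 285 ± 68.2 normalised CPM (SD, n = 3) and Mst84Db from 0.196 to 654 ± 132. These genes took 1.46 ± 0.0639% of the counts of the IPs and 2.33% of the control's. All 10 ejaculatory duct and bulb genes were higher (median 8.94, adjusted p = 0.0205; adjusted p = 0.430 with an estimated correlation), among them Dup99B (10.77 ± 0.41, adjusted p = 7.28e-08), and took 0.597% of the counts in the IPs and 0.958% in the control. Of 15 fat body genes 14 were higher and none lower, with a median of 5.86, or 5.53 at the bound (adjusted p = 0.0224; adjusted p = 0.430 with an estimated correlation), such as the iron carrier Tsf1 (9.99 ± 0.59, adjusted p = 7.10e-07). Of 29 cuticle genes 23 were higher and 3 lower, with a median of 4.23, or 3.99 at the bound (adjusted p = 0.0445; adjusted p = 0.430 with an estimated correlation). In every list of this comparison the counts adjusted over the list alone were the same.

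Main cell genes were also higher in the IPs without a list-wide call. Of 20 genes 17 were higher and 1 lower (median 3.17, adjusted p = 0.403), and of 51 other seminal fluid proteins 45 were higher and 3 lower (median 3.35, adjusted p = 0.0735). The main cell list, Acp32CD included, took 5.175% of counts in the IPs and 4.807% in the control. The other seminal fluid proteins took 2.886% and 2.565%, so RNA of both lists was also present without tagged ribosomes. Sex Peptide, SP, was 15.8-fold higher (3.99 ± 1.15, adjusted p = 0.0108). It differed among the wild-type libraries, with 0.978, 63.8 and 81.4 CPM, and the main cell list lay lower in wild-type replicate 1 than in replicates 2 and 3 by a median of -5.55 on the log2 scale in 19 of 19 genes.

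After scaling, Hox, stress and secretory genes were higher in the sorted cells. The TMM factors were 0.618, 0.583 and 0.544 in wild type and 1.62, 1.71 and 1.85 in the IPs. All 6 Bithorax genes were lower in the IPs, with a median of -5.61 (adjusted p = 0.00194; adjusted p = 0.430 with an estimated correlation), Ubx by -9.56 ± 0.64 (adjusted p = 1.64e-06), abd-A by -5.46 ± 0.22 (adjusted p = 8.84e-08) and iab-8 by -4.36 ± 0.32 (adjusted p = 2.97e-06). Of 10 secondary cell factors 7 were lower and 2 higher (median -2.80, adjusted p = 0.0224; adjusted p = 0.430 with an estimated correlation). Of 15 stress-induced chaperones 13 were lower and 1 higher, with a median of -5.02 (adjusted p = 4.01e-05; adjusted p = 0.685 with an estimated correlation), stv by -6.99 ± 0.30 (adjusted p = 1.13e-07). Of 38 translocation and coat genes 34 were lower and 2 higher (median -1.42, adjusted p = 6.47e-08; adjusted p = 0.430 with an estimated correlation), among them the coatomer subunit beta'COP (18.4-fold lower). Of 27 ER folding genes 18 were lower and 2 higher (median -1.05, adjusted p = 6.30e-04; adjusted p = 0.743 with an estimated correlation), with the transcription factor Xbp1 8.67-fold lower. Before scaling, the translocation and coat list took 0.421% of counts in wild type and 0.478% in the IPs. The ER folding list took 0.433% and 0.581%, so both falls appear only after scaling. The Bithorax (0.318% and 0.0151%), secondary cell factor (0.243% and 0.0834%) and stress (1.998% and 0.249%) lists were lower in the IPs before scaling too.

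Of 92 ribosomal genes 76 were lower and 9 higher, with a median of -1.13 (adjusted p = 1.41e-08; adjusted p = 0.844 with an estimated correlation), the 9 including RpL10Aa, which was at 1 count in sorted cells and 104 ± 13.7 normalised CPM in the IPs. The bait gene RpL10Ab did not pass here (0.70 ± 0.32, adjusted p = 0.0669), but did with RLE factors (1.03, adjusted p = 0.0137), with DESeq2 (1.03, adjusted p = 0.00115) and without IP replicate 1 (1.12, adjusted p = 7.08e-04). Of 31 proteasome genes 17 were lower and 1 higher (median -0.55, adjusted p = 5.77e-04; adjusted p = 0.844 with an estimated correlation). Of 73 translation factor and tRNA synthetase genes 50 were lower and 15 higher, with a median of -1.30 and a mean of 0.23 (adjusted p = 4.23e-05; adjusted p = 0.629 with an estimated correlation). The median over all tested genes was 0.76 in this comparison and moved to 1.11 with RLE and 0.43 with upper-quartile factors, which turned the direction of none of these medians. Before scaling, the ribosomal list took 1.77% of counts in wild type and 2.29% in the IPs. The proteasome list took 0.242% and 0.457%, and the translation factor and tRNA synthetase list 0.789% and 0.945%. The falls of these 3 lists therefore appear only after scaling.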

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

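The items below were picked out by a rule that marks a difference between the effects of the 2 mutants, tested by the direct D1 against miP contrast. The contrast was planned, but the 3 genes named here were picked after their values were seen, because they passed against wild type in opposite directions, and that choice fixes a difference between their effects. By that contrast 554 genes were higher in D1 and 313 lower. For these genes the difference between the effects on the log2 scale was 3.67 for nSyb, 9.90 for ppk20 and 9.76 for CG9119. These 3 were higher in D1 than in wild type and lower in miP.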

How the results depend on the processing

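The settings without replicate 1 of both mutants, with these libraries or replicates 2 and 3 alone, and with a block in the 6 mutant libraries were chosen only after the data were seen. With replicate 1 alone, each mutant is represented by 1 library, which is assumed to vary like the other groups, and D1 against miP compares 1 library with 1. Every gene list call rests on the preset correlation: 42 of 175 tests passed with it and 0 with an estimated correlation, which is 0 in each of the 5 comparisons. Without replicate 1 of both mutants the lists past 0.05 in miP against wild type went from 3 to 6.

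For D1 against wild type (505 higher, 298 lower), DESeq2 gave 859 higher and treat 197 higher and 78 lower. Leaving out 1 library gave 233 to 1093 higher and 137 to 1002 lower. Both mutants' replicate 1 left out gave 1416 and 1444, that replicate alone 1249 and 1456, and replicates 2 and 3 alone 1425 and 1462. For miP against wild type (2 higher, 5 lower), DESeq2 gave 9 and 26, RLE factors 3 lower, upper-quartile factors 3 lower, treat 0 and 3, and leaving out 1 library 0 to 0 higher and 0 to 3 lower. Both mutants' replicate 1 left out gave 361 and 632, that replicate alone 1 and 1, and replicates 2 and 3 alone 373 and 668.

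For D1 against miP (554 higher, 313 lower), DESeq2 gave 855 and 541, only the 2 groups compared 336 and 139, treat 210 and 89, and leaving out 1 library 334 to 907 higher and 191 to 614 lower. Both mutants' replicate 1 left out gave 1007 and 732, that replicate alone 860 and 1091, and replicates 2 and 3 alone 1022 and 749. For the ribosome IPs against the control (414 higher, 34 lower), DESeq2 gave 927 and 135, all 13 libraries in the fit 213 and 4, treat 52 and 2, no filter 57 lower, and leaving out 1 library 1 to 1433 higher and 0 to 481 lower. The IPs against sorted cells kept both counts within 1.5 times in every setting.

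The replicate block gave 1 higher and 3 lower genes for miP against wild type, where pairing by number was not settled. It also took the glycosylation list past 0.05 in D1 against wild type (adjusted p = 0.0428), where the same-number values of r were all negative. In D1 against miP, where pairing was not settled either, the block gave 538 and 337, and 593 and 346 in the 6 mutant libraries. Among the 31 genes recomputed for that contrast the block changed the call of Ubx alone. Among the list tests, run with the block in the 9 sorted libraries, it changed that of the translocation and coat list alone. Genes called in both mutants in the same direction went from 2 to 9 with DESeq2, 1 at a threshold of 0.01 and 1 with the replicate block, and those in opposite directions from 3 to 11 with DESeq2 and 1 at 0.01.

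Values of genes that were not called turned direction in 7 cases, and the cause was not tested. Abd-B in D1 stood at 0.18 with replicate 1 alone. In miP, Ubx ranged from -0.00038 to 0.14 and iab-4 from -0.092 to 0.24 with 1 library left out, and iab-4 stood at -0.21 with replicate 1 alone. In the IPs against the control, Abd-B ranged from -0.064 to 0.69 and bxd from -0.71 to 0.28.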

Other observations

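Genes lower in D1 and genes enriched on the ribosomes of the driver's cells overlapped. Of 239 genes lower in D1 and at or above the level of 5 CPM set for this test, 29 (12.1%) were higher in the IPs than in their control. Among 4689 genes called in neither direction the share was 4.07%. Against all genes considered that were not lower in D1, the odds ratio was 2.96 (interval 1.89 to 4.49). The 29 genes included CG13822, iab-8, lectin-46Ca, CG7713 and the zinc transporter Zip88E. Genes higher in D1 were also over-represented (34 of 354, odds ratio 2.27 against all genes not higher in D1), so the overlap was not particular to losses.

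The tests of length, main cells, carry-over, fat body, CR40469 and position near the Bithorax complex were chosen only after the results were seen. Those of control depth, of the overlap above and of the splits were chosen before. With 10 regroupings of 3 against 3 libraries, the share of splits with as many calls can never be below 0.05. The real split alone reached its number in each of the 4 comparisons tested: 1 split of 10 for D1 against wild type, 1 for miP against wild type, 1 for D1 against miP and 1 for the IPs against sorted cells, with 0 calls in the highest other split.

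Replicate 1 of both mutants stood apart from replicates 2 and 3. Short transcripts were higher in it, with a Spearman rho between exonic length and its difference of -0.63 in D1 and -0.366 in miP, so differences in RNA integrity or amplification may contribute. RNA of main cells could also contribute, since the main cell list had medians of 2.47 and 0.429, yet in miP this is small beside the ribosomal shift. The 2 were not separated here.

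Of the genes enriched in the IPs, 119 were under 1 CPM in every wild-type sorted library, among them sad, Tsf1 and CG32557. At the level of the IPs the control would have held a median of 180 counts over these genes (lowest 15.9), and it held a median of 20. A gene could be called higher only where the control held clearly fewer counts than the IPs predict. These values therefore cannot decide whether the low depth of the control contributes. Of the testis, duct, muscle and main cell lists, the highest median against the control was -0.023, so these lists as a whole were not raised. Only 1 of the 119 genes is on these 4 lists or those of fat body, hemocytes or neurons. The medians therefore cannot decide whether carry-over of such RNA accounts for the 119 genes. Fat body RNA may contribute, with a list median of 1.55, though only 2 of its 16 genes were higher and 1 lower. Tagged ribosomes in driver-positive cells that the sort did not recover were not tested.

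CR40469 was near 0 in both mutants. Its level differed 289-fold between the highest and lowest ribosome IP, all of 1 stated genotype, so a variant segregating in the stocks may explain it. Of 7 libraries with an intact micropeptide locus, 2 were under 10 CPM, so loss of MSAmiP is not needed for a low level, although it could still act in miP.

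D1 calls within 2 Mb of the Bithorax complex, where variants linked to the lesion would lie, had an odds ratio of 1.38 (38 of 300 genes, interval 0.944 to 1.96).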
